A study of Oryza sativa with 12 samples.

How the data were processed

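Anthers at stages S8-9 of wild-type and ago1d rice kept at 28 °C or 22 °C gave 12 degradome libraries, 3 biological replicates in each of 4 groups, grouped by the genotype and temperature in the labels. Per the series design text, the authors ligated adapters to fragments with a 5′ monophosphate from poly(A) RNA, removed adapter sequence from the reads, mapped them with bowtie to the MSU v7.0 rice genome, and ran CleaveLand4 and GSTAr with 3116 small RNAs. The submitters' processing notes also name Bowtie, and its version is not given in the sources used here. The deposited tables, 1 per temperature, give each pair of a small RNA and a transcript with 6 sets of library columns, replicates not pooled.

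Per the file headers, the deposited signal of a library is the number of normalised reads that start at the slice position, scaled by the authors' software to a common depth that the headers do not state. Low values showed that depth in relative terms. In each library every value was a whole multiple of the smallest value within a tolerance of 0.001 (100% of values), and values of 1 multiple were exactly those of category 4, which stands for 1 read. So 1 read was worth 18.3 to 22.5, whole reads were recovered by division, and the relative depth of the libraries was 81.5% to 100%. Total reads per library are unknown, so precision is known only for the listed sites, with 6985 to 10225 reads per library. Per the file headers, the deposited score is the pairing penalty of small RNA and target (0 for a perfect match, up to 5 here), the deposited ratio is the free energy of the pairing over that of a perfect match (at least 0.651 here), and the deposited p-value of each library is that of CleaveLand for a position of its category. The tables also list the direction of each small RNA at stages S7-8 and S9 as up, down or non, and the headers do not say against what.

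Several small RNAs can be listed at 1 site. In no library did 2 of them carry reads at the same site, so the value of a site was taken as the largest of its pairs. At 22 °C 84.3% and at 28 °C 70.9% of the zeros in pairs that reach 200 were filled by another small RNA at the same site. Where that small RNA has no listed pair, a 0 may stand for reads listed elsewhere. Small RNAs were linked if listed together at a site at either temperature, without a comparison of their sequences. The 9 linked pairs of small RNAs left 19 sites at 28 °C and 11 at 22 °C with such a missing partner. Sites on several transcript forms of a gene are not independent of each other. 1 line of the 22 °C table without a small RNA or gene was left out; it holds 1 read in 1 library.

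The design assumed counts or normalised values; the tables held a normalised signal, so limma-trend on log2(value + 1) was the test, per site, on the groups compared, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on that scale. At low sites with some libraries at 0 the log2 change can be larger than that of the group means or differ from it in sign. edgeR (quasi-likelihood) and DESeq2 on the recovered reads were added after the data were seen. edgeR called 1 site at 28 °C and 5 at 22 °C, and DESeq2 0 and 2. The temperatures were compared on the 206 sites in both tables, on the assumption that both tables were scaled to the same depth. The value of 1 read lay in a similar range in both, which does not show that the depth is the same. Directions over sites were tested with a two-sided exact sign test over genes, class medians and correlations with 100000 permutations, and gene lists with camera. In the added comparison of detection, pairs with a p under 0.05 in a wild-type library were looked up in the other wild-type libraries and in ago1d, with intervals from 10000 bootstrap samples of genes. Small RNA classes follow the names in the tables.

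Named sites followed a rule set before the data were examined: of the sites past the threshold that moved the same way in every replicate, up to 10 falls and 10 rises per table with 1 site per gene, the 5 sites with the highest wild-type value, and all detected members of the lists with gene IDs. The files do not pair the gene IDs with names, and 0 of the 543 IDs matched the gene table used here, so at most 2 IDs that rose and 2 that fell are printed per comparison, and other sites are named by their small RNA. The 23 lists defined by gene descriptions had no descriptions to search and gave no result. Positions are counted on the MSU v7.0 transcripts; genome coordinates and exons were not analysed here.

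On simulated tables of 426 sites with 200 changed ones, limma called 89.7% of 4-fold lowered sites with over 50 reads at 28 °C and 86.2% at 22 °C, and 8.3% and 9.83% of its calls were unchanged sites, above the nominal level. For edgeR the shares were 100% and 98.5%, with 0.91% and 0.65% unchanged. The spread between simulated replicates was assumed and the same for all sites. These shares depend on it and on the number of changed sites, so they may not hold for the real libraries. In simulated tables of assumed read numbers, filtered on at least 3 reads in a wild-type library (the deposited tables also keep pairs with 1 read), with no change, 56.4% of the listed sites were lower in the other group while the detection difference was -0.08 ± 0.58 points; with all sites lowered to 50% it was -13.05 ± 0.83 points.

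Alternatives set before the data were examined covered the replicate block, scaling, pseudocounts of 0.5 and 5, a minimum of 10 reads, score and category limits, pairs or genes in place of sites, and each replicate left out. Those added later were the count tools, a pseudocount of 20, zeros taken as missing, thinned reads, other class borders and all alternatives of the temperature comparisons. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.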

Results

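Degradome sequencing reads the 5′ ends of uncapped, polyadenylated RNA fragments, so that an mRNA sliced under the guidance of a small RNA leaves reads that start at the slice position. The libraries came from rice anthers (cultivar Nipponbare) of the wild type and of ago1d, a CRISPR/Cas9 mutant of the Argonaute gene AGO1d, from plants kept at 28 °C (the normal temperature) or 22 °C (the low temperature) during anther development. Each of the 4 groups held 3 biological replicates, 12 libraries in all. The question, from the series title, is whether 21-nt phasiRNAs, small RNAs cut in register from long anther transcripts, slice mRNAs through AGO1d in a way that matters for fertility at different temperatures.

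The table for 28 °C listed 443 pairs of a small RNA and a target, on 426 sites (a transcript and a slice position) of 352 genes. The table for 22 °C listed 451 named pairs on 426 sites of 363 genes. Values were normalised degradome reads, and 1 read was worth 18.3 to 22.5 of them in the 12 libraries. The listed sites held 6985 to 10225 reads per library, and the relative depth of the libraries lay between 81.5% and 100% of the deepest. AGO1d itself was no listed target, so its transcript was not measured and gave no check of the genotype labels. Every listed pair had a degradome p-value under 0.05 in at least 1 wild-type library and none needed a read in ago1d, which favours lower values in ago1d throughout these tables.

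miRNA sites carried most of the cleavage signal in both genotypes. In the wild type they held 77.6% of the listed value at 28 °C and 81.1% at 22 °C, with 64 sites in each table. The miR160 family, which targets auxin response factor mRNAs in plants, led with 99483 ± 9191 normalised reads in the wild type and 82019 ± 3806 in ago1d at 28 °C (SD, n = 3), summed over 9 sites of 5 genes. Sites listed at 0 in some libraries, discussed further on, lower that ago1d sum. At 22 °C the sums over 8 sites were 115649 ± 6460 in the wild type and 121502 ± 3530 in ago1d. The miR396 family, whose known targets are growth-regulating factor mRNAs, came next with 13760 ± 1913 in the wild type and 12431 ± 1302 in ago1d at 28 °C, and with 15024 ± 1159 and 10822 ± 1918 at 22 °C, where such zeros also lower the ago1d sum. At 22 °C the miR171 sites held 5069 ± 252 in the wild type and 4999.5 ± 360.6 in ago1d, and the miR162 site, on a family that targets Dicer-like 1 mRNA, 3900 ± 612 and 3378 ± 318. These family sums were not tested.

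Sites of 21-nt phasiRNAs were the most numerous and the weakest. They made up 246 of the 426 sites at 28 °C and 266 of the 426 at 22 °C, and held 5.7% and 4.9% of the wild-type value. Their median site had 1.0 read per wild-type library at both temperatures, against 18.3 and 19.3 reads for miRNA sites. Summed over all their sites, 21-nt phasiRNAs gave 9755 ± 482 normalised reads in the wild type and 7052 ± 701 in ago1d at 28 °C, and 9058 ± 785 and 7213 ± 424 at 22 °C (SD, n = 3); the choice of pairs on wild-type reads enters these sums.

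**Figure D1:**
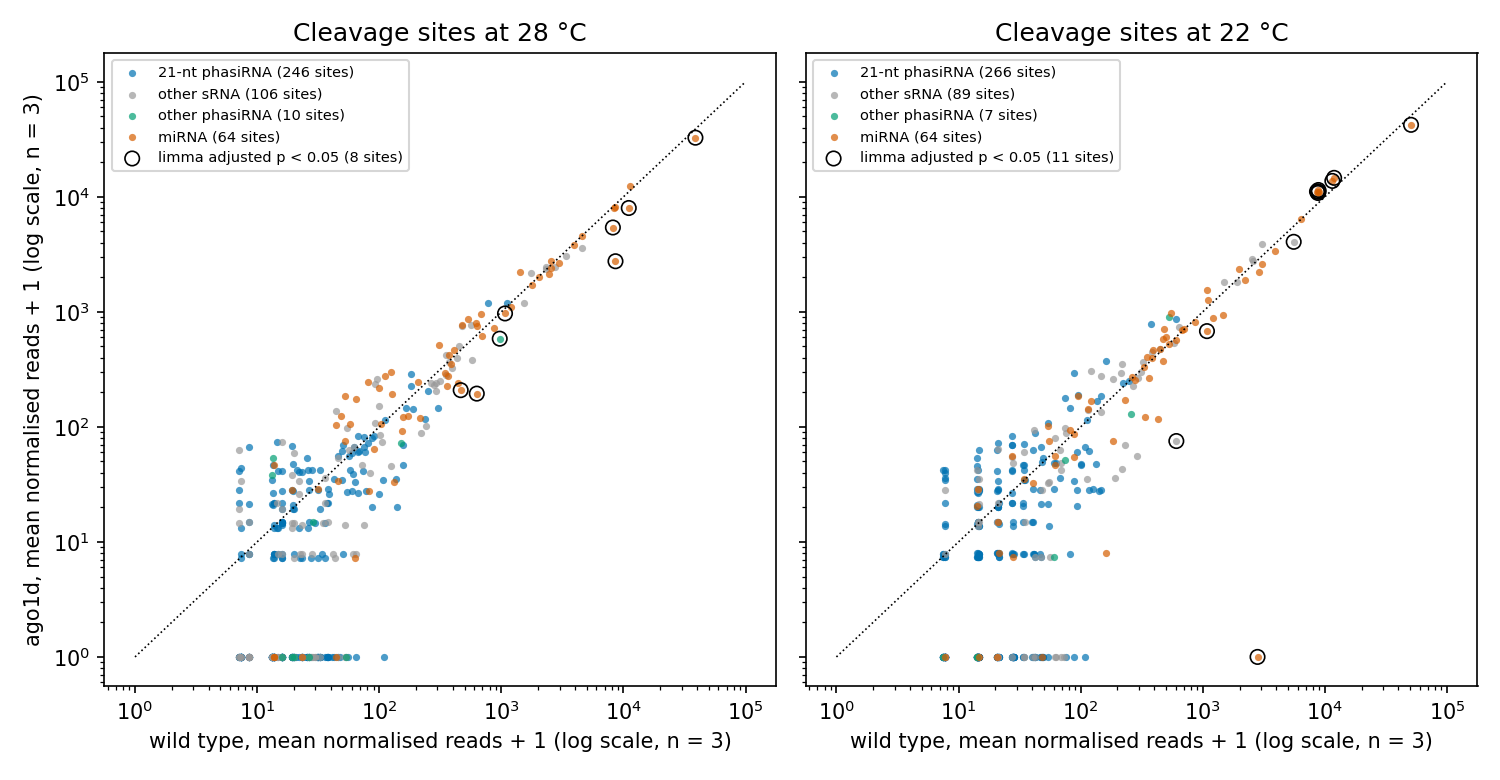
Each point is 1 cleavage site, with the wild-type mean on the x axis and the ago1d mean on the y axis (normalised reads + 1, log scales, n = 3 libraries each), at 28 °C (left) and 22 °C (right). Colours give the small RNA class, open circles the 8 and 11 sites past the limma threshold, the dotted line equal values, and the points at the bottom the 169 and 163 sites with no read in ago1d.

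The first comparison asked which sites were cleaved differently in ago1d at 28 °C. The most heavily cleaved site of the table, the miR160 site of LOC_Os10g33940.1, fell from 38854 ± 4263 normalised reads in the wild type to 32653 ± 227 in ago1d (SD, n = 3). The log2 change was -0.24 with a standard error of 0.07 (limma adjusted p = 0.0227), though it stood at 0.01 in edgeR with DESeq2 size factors. Quantile normalization gives the highest site of every library the same value, so its 0.0 here does not bear on the fall. The other 7 of the 8 sites that passed were also lower in ago1d, but each was listed at 0 in at least 1 ago1d library. One of them, the miR160 site of LOC_Os06g47150.4, was listed at 8257, 0 and 0 in the ago1d libraries and at 7927, 8865 and 9022 in the wild type. These 7 sites belong to miR160, miR396, miR166 and a 22-nt phasiRNA. At all 7, another small RNA that is listed together with theirs elsewhere has no listed pair (sequences were not compared). With these zeros taken as missing, 1 site passed, LOC_Os10g33940.1. The second most cleaved site of the table, on another gene and also under miR160, held 11254 ± 947 in the wild type and 12352 ± 1124 in ago1d without passing.

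In all, 8 of 426 sites passed in limma, 8 lower and 0 higher (1 lower and 1 higher with quantile normalization), and 15 had an unadjusted p under 0.05 where chance would give 21.3. On the recovered whole reads edgeR called 1 site and DESeq2 called 0, with 6 and 3 sites at an unadjusted p under 0.05. The fall at LOC_Os10g33940.1 did not pass in either (edgeR adjusted p = 0.65, DESeq2 adjusted p = 0.986), nor in limma when any 1 library was left out (log2 changes of -0.34 to -0.20, adjusted p 0.138 to 0.691), and no call at all was left in limma without wild-type replicate 1, 2 or 3. Without ago1d replicate 1, 2 or 3 there were 5, 8 and 6 calls. Leaving out a wild-type library left sites with no read in any other library, since wild-type reads chose the pairs. Without wild-type replicate 1, 266 sites were lower and 111 higher of 426. Sites at 0 throughout enter limma's estimate of spread, so this loss of calls is no clean test of them.

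At 22 °C the largest change among the passing sites with no library at 0 was at the site of LOC_Os02g18750.1 paired with a 22-nt small RNA of no named class (other_22_seq216). It fell from 607 ± 155 normalised reads in the wild type to 74.3 ± 63.5 in ago1d (SD, n = 3), 8.17-fold lower, with a log2 change of -3.37 and a standard error of 0.71 (limma adjusted p = 0.000876), with less transcript and less slicing not told apart by these reads. The miR160 site of LOC_Os10g33940.1 fell from 50762 ± 4592 to 42246 ± 2954, a log2 change of -0.26 with a standard error of 0.04 (limma adjusted p = 3.98e-07). As the highest site it was again set to 0.0 by quantile normalization, whatever its change. Against this fall, other miR160 sites rose. That of LOC_Os06g47150.4 went from 8857 ± 409 to 11458 ± 386, a log2 change of 0.37 with a standard error of 0.09 (limma adjusted p = 0.00363). That of LOC_Os02g41800.1 went from 11908 ± 1300 to 14609 ± 1315, a log2 change of 0.30 with a standard error of 0.08 (limma adjusted p = 0.0114). With quantile normalization they stood at 0.0 and 0.03. That is a weak check, since it sets values by rank and both were among the 5 sites highest in the wild type.

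Altogether 11 of 426 sites passed at 22 °C, 5 lower and 6 higher, and 35 had an unadjusted p under 0.05 against 21.3 by chance. Scaling changed that balance in either direction: 4 lower and 0 higher with median scaling, 4 and 1 with quantile normalization, and 3 and 2 without scaling. edgeR gave 3 and 2, with TMM 2 and 0, and with DESeq2 size factors 2 and 6. The 6 rises were transcript forms of 2 genes, LOC_Os06g47150 and LOC_Os02g41800. A site of other_21_seq552, a small RNA with a stretch of miR171, fell by 0.45 on the log2 scale with a standard error of 0.14 (limma adjusted p = 0.0488). The remaining 2 falls, both under miR396, were listed at 0 in ago1d libraries. The fall at LOC_Os02g18750.1 also passed in edgeR (adjusted p = 1.8e-05) and DESeq2 (adjusted p = 0.0189), which called 5 and 2 sites. The fall at LOC_Os10g33940.1 passed in edgeR (adjusted p = 0.00528) but not in DESeq2 (adjusted p = 0.118). So did the rise at LOC_Os06g47150.4 (0.037 and 0.197). The rise at LOC_Os02g41800.1 passed in neither (0.102 and 0.606), nor did the fall under other_21_seq552 (0.0751 and 0.66). In limma the fall at LOC_Os02g18750.1 missed the threshold without wild-type replicate 1, 2 or 3 (adjusted p up to 0.466), with log2 changes of -3.23, -3.29 and -3.60. So did the fall at LOC_Os10g33940.1 (adjusted p up to 0.489), with -0.32, -0.19 and -0.28. Without any 1 ago1d replicate both falls passed (limma adjusted p up to 0.0133 and 0.0178). As at 28 °C, leaving out a wild-type library left sites with no read at all, so it is no clean test of these falls. The fall under other_21_seq552 and the rises at LOC_Os06g47150.4 and LOC_Os02g41800.1 missed the threshold when any 1 library was left out (for the rises, log2 changes of 0.34 to 0.40 with adjusted p 0.0615 to 0.422, and of 0.22 to 0.38 with adjusted p 0.053 to 0.489). Quantile normalization moved all sites up by a median of 0.42 at 28 °C and 0.44 at 22 °C on the log2 scale, and DESeq2 size factors in edgeR by 0.22 and 0.11.

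**Figure D2:**
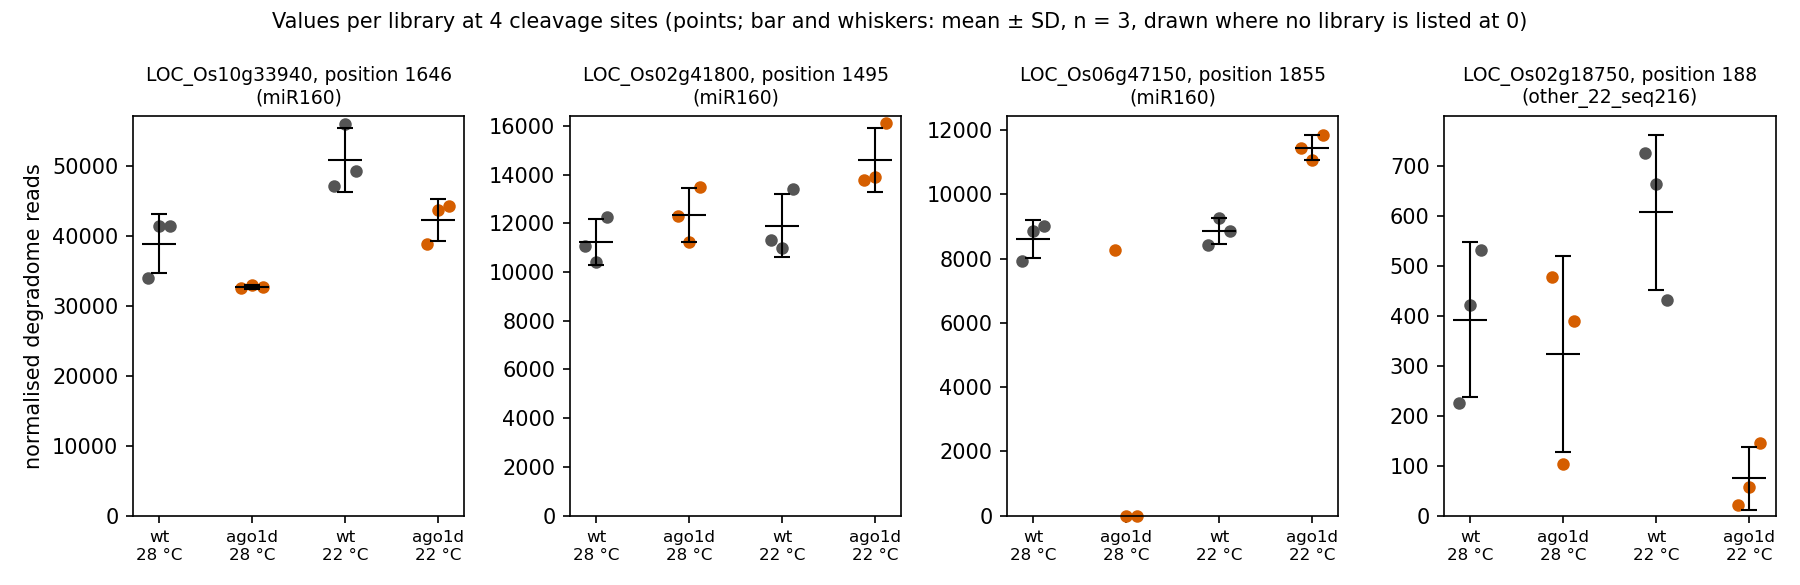
Normalised degradome reads (y axis, from 0) of each library at 4 sites, wild type in grey and ago1d in orange, with the mean and SD of 3 libraries where none is listed at 0. At 22 °C the ago1d libraries at LOC_Os02g18750.1 lie at 21.0, 57.3 and 144.5, below the wild-type values of 726, 662.5 and 431.5, and at LOC_Os06g47150.4 the libraries at 0 are those of ago1d at 28 °C.

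No 21-nt phasiRNA site passed at either temperature. At 28 °C, limma called 0 of 246 such sites with 3 at an unadjusted p under 0.05, and the smallest adjusted p was 0.713; at 22 °C it called 0 of 266 with 13 at an unadjusted p under 0.05, and the smallest adjusted p was 0.207. edgeR, with 2 and 6 sites at an unadjusted p under 0.05, and DESeq2 also called 0 at both temperatures. The most cleaved site of the class, under 21_PHAS_phasi21_seq393, held 1103 ± 312 normalised reads in the wild type and 1182 ± 112 in ago1d at 28 °C, and 601 ± 224 and 870 ± 236 at 22 °C. The most cleaved of the sites of 21_PHAS_phasi21_seq2003 held 772 ± 167 and 1193 ± 364 at 28 °C, and 375.5 ± 53.5 and 789 ± 70 at 22 °C (limma adjusted p = 0.23). A site of 21_PHAS_phasi21_seq1021 at 22 °C was listed at 0, 19.1 and 61.9 in ago1d and at 196.2, 140.5 and 102.7 in the wild type without passing (limma adjusted p = 0.23). These sites were chosen after their values were seen, and most sites of the class were far weaker. Of 4-fold lowered sites with under 5 reads in simulated data, limma called 6.2% at 28 °C and 7.5% at 22 °C, against 22.8% and 35.0% with 5 to 50 reads and 89.7% and 86.2% with over 50. The spread of these simulated data was assumed.

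Among miRNA sites short of the threshold at 22 °C, a site of miR408, a family with targets among copper proteins, was listed at 21.0, 0 and 0 in ago1d and at 215.9, 80.3 and 184.9 in the wild type (limma adjusted p = 0.0648), and passed without ago1d replicate 1 (limma adjusted p = 0.0447). A site of miR528 held 425.5 ± 180.9 normalised reads in the wild type and 115.8 ± 36.1 in ago1d (limma adjusted p = 0.207), and that of miR398 1477 ± 340 and 935 ± 270 (limma adjusted p = 0.334). These sites were chosen after their values were seen.

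Over all sites, more were lower than higher in ago1d. At 28 °C 318 sites (74.6%) were lower and 108 higher, and at 22 °C 300 (70.4%) were lower and 126 higher. Across genes, which are not replicates, 268 were lower and 84 higher at 28 °C (two-sided exact sign test, p = 1.59e-23), and 265 and 98 at 22 °C (two-sided exact sign test, p = 6.98e-19). The median site of every ago1d library was at 0.0 on the log2(value + 1) scale, against 4.27 to 5.04 in the wild type at 28 °C and 4.40 to 5.33 at 22 °C (exact permutation p = 0.1 at both, the smallest that 3 against 3 can give). Of sites with under 5 reads per library, 78.6% were lower at 28 °C and 78.1% at 22 °C. With 5 to 50 reads the shares were 57.1% (36 of 63) and 38.3% (23 of 60), and with over 50 reads 65.4% (17 of 26) and 41.7% (10 of 24). With at least 10 reads over the libraries, 58.6% were lower at 28 °C and 47.2% at 22 °C, and the sign test no longer passed (exact p = 0.12 and 0.93).

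Because wild-type reads chose the pairs, their detection was compared in libraries that had no part in the choice, an analysis added after the values were seen. Detection was counted per pair, so a 0 can stand for reads listed under another small RNA at the same site. Of the pairs with a p under 0.05 in a given wild-type library, 50.9% had a read in the other wild-type libraries and 52.6% in ago1d at 28 °C, a difference of 1.7 percentage points (95% bootstrap interval over genes, -1.3 to 4.7). At 22 °C it was 52.5% and 50.3%, a difference of -2.2 points (-6.1 to 1.7). For 21-nt phasiRNAs the shares were 35.0% and 37.0% at 28 °C, a difference of 1.9 points (-2.9 to 6.5), and 40.8% and 37.0% at 22 °C, a difference of -3.8 points (-9.8 to 2.0). Thinning the wild-type reads to 50% would move the 21-nt phasiRNA share by -7.0 points at 28 °C, outside that interval, and by -9.8 points at 22 °C, at its edge. The change of the 21-nt phasiRNA difference between the temperatures, -5.8 points, had an interval of -13.1 to 1.7.

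**Figure D3:**
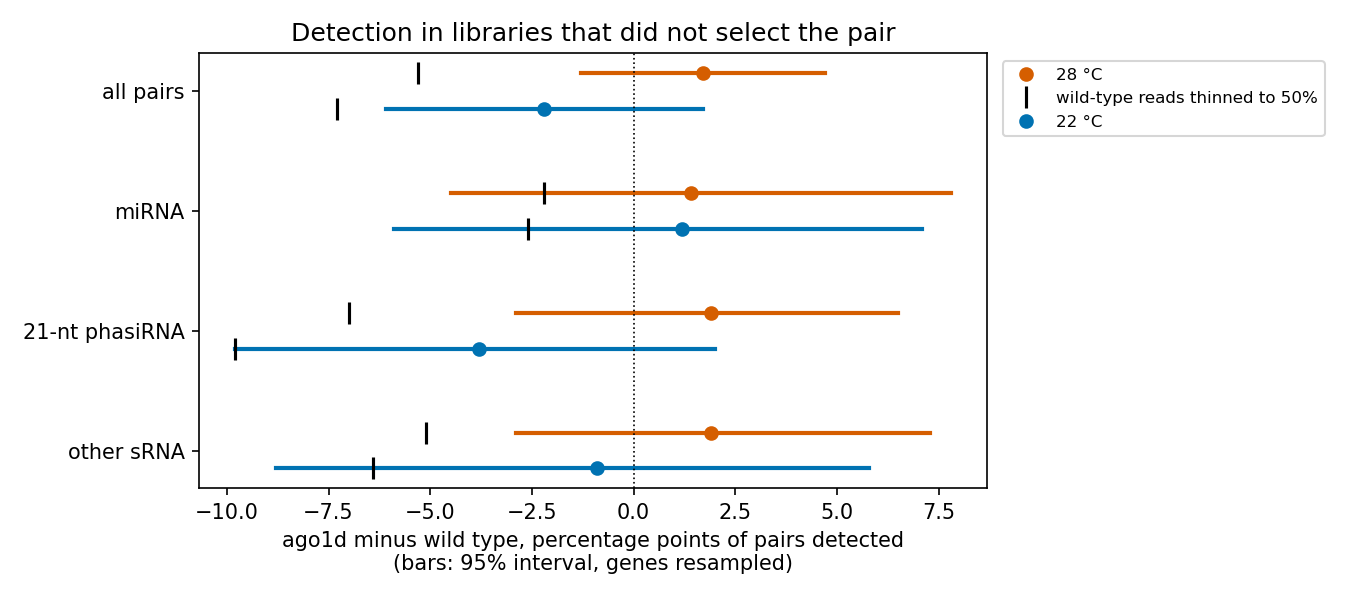
Points give the difference between ago1d and the wild type in the percentage of pairs with a read, in libraries that did not select the pair, at 28 °C (orange) and 22 °C (blue); bars are 95% bootstrap intervals over genes and black ticks the difference that wild-type reads thinned to 50% would give. All 8 intervals include 0, and for all pairs both ticks (-5.3 and -7.3 points) lie outside them. The intervals resample genes and do not cover the spread between libraries.

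By small RNA class, 21-nt phasiRNA sites had a lower median log2 ratio than miRNA sites in these tables, whose pairs were chosen on wild-type reads and whose 21-nt phasiRNA sites have the fewer reads. In libraries that did not select the pairs, the mean log2 difference at 28 °C was 0.09 for 21-nt phasiRNAs (95% bootstrap interval, -0.18 to 0.35) and 0.03 for miRNAs (-0.58 to 0.66). At 22 °C it was -0.17 (-0.51 to 0.16) and 0.16 (-0.59 to 0.78). These means are per pair, and the miRNA values include zeros of pairs whose site was listed under another small RNA. Over all libraries, each gene took the class of its site with the highest wild-type value and the median ratio of all its sites. At 28 °C the median was -1.52 for 221 genes classed as 21-nt phasiRNA and -0.13 for 47 classed as miRNA. The difference was -1.39 (permutation p = 0.00037, adjusted 0.00111 over 6 class comparisons). At 22 °C the medians were -1.47 and -0.18, a difference of -1.28 (permutation p = 0.00406, adjusted 0.00812). Other small RNAs, mostly of no named class, did not differ from 21-nt phasiRNAs (permutation p = 0.252 at 28 °C and 1 at 22 °C). At 28 °C the difference was -0.50 among sites with at least 10 reads (permutation p = 0.0385) and -1.71 among sites under 5 reads per library (permutation p = 0.0015); at 22 °C it was 0.24 (permutation p = 0.207) and -0.89 (permutation p = 0.0763). Among sites of category 0 in a wild-type library, also chosen on wild-type values, it was -1.80 at 28 °C and -1.72 at 22 °C (permutation p = 0.00064 and 0.00072). Over all sites the difference missed the threshold without wild-type replicate 1 or 2, at -1.02 and -0.80 at 28 °C and at -0.55 and -1.05 at 22 °C.

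Degradome categories rank a site against the other positions of its transcript, with category 0 for a sole maximum. Category 0 sites numbered 76.0 ± 3.6 per wild-type library and 64.0 ± 3.0 per ago1d library at 28 °C, and 73.3 ± 2.1 and 60.0 ± 1.0 at 22 °C (SD, n = 3). Category 1 sites, which share the maximum with another position, numbered 20.3 ± 4.7 and 4.0 ± 1.7 at 28 °C and 15.7 ± 2.1 and 3.3 ± 1.2 at 22 °C. Sites with no read numbered 176 ± 8.4 per wild-type library and 246 ± 3.0 per ago1d library at 28 °C, and 166 ± 8.7 and 243 ± 9.0 at 22 °C. These counts were not tested, and the selection on wild-type reads enters them as well.

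Of the gene lists fixed before the data were examined, the anther and tapetum regulators had 2 of 8 genes in both tables, with 5 sites. None passed: limma called 0 sites, and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 at either temperature, and edgeR and DESeq2 called 0. At 22 °C the 4 sites on forms of the gene entered in the list as GAMYB, a MYB factor needed for anther development, held 181.5 to 295 normalised reads in the wild type and 260.5 to 348 in ago1d on average, and at 28 °C 263 to 290.4 and 205 to 241. The gene entered as TDR, a tapetum regulator, had a 21-nt phasiRNA site listed at 22.5, 0 and 0 in the wild type and at 41.5, 0 and 0 in ago1d at 28 °C. As a set, the list did not stand apart at 28 °C (camera p = 0.602, p = 0.686 with an estimated correlation) or at 22 °C (camera p = 0.0964, p = 0.322 with an estimated correlation). Of the 5 Argonaute genes, AGO1a had a miR168 site at 22 °C, with 19.6, 40.2 and 184.9 in the wild type and 84.1, 133.7 and 61.9 in ago1d (limma adjusted p = 0.742). The lists of pollen wall and lipid genes and of meiosis genes, with 6 and 2 members, had 0 detected genes.

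The temperatures shared 206 of their 426 sites each, 48.4%. miRNA sites were shared most, 50 of 64, and 21-nt phasiRNA sites least among the large classes, 102 of the 246 at 28 °C and of the 266 at 22 °C. Detection also differed between these classes within a temperature. Of 21-nt phasiRNA pairs chosen by a wild-type library, 35.0% at 28 °C and 40.8% at 22 °C had a read in the other wild-type libraries. For miRNA pairs the shares were 71.8% and 62.9%. These miRNA shares are lowered by the listing: 78 miRNA pairs at 28 °C and 84 at 22 °C lay on 64 sites each. Only 1 small RNA of a site carried reads in a library. The sharing therefore does not separate temperature from detection. Of genes, 172 were in both tables, and of small RNAs 163. Pairs of category 2 or lower with over 1 read in a wild-type library at both temperatures numbered 132, on 90 genes: 58 of miRNAs, 38 of 21-nt phasiRNAs, 2 of other phasiRNAs and 34 of other small RNAs. With the score limit to 4, 60.5% of the sites of 28 °C were shared, and with category 0 in a wild-type library 62.8%.

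On the 206 shared sites, the effect of ago1d at 22 °C was compared with that at 28 °C. A single site passed in limma, with 9 at an unadjusted p under 0.05 where chance would give 10.3: position 581 of LOC_Os02g47280.2 under miR396, listed at 0 in all 3 ago1d libraries at 22 °C. In the same libraries another form of the gene, cut at position 678, held 1788, 2407 and 2457, and with such zeros taken as missing 0 sites passed in limma (13 at an unadjusted p under 0.05). At the other_22_seq216 site of LOC_Os02g18750.1 the ago1d libraries at 28 °C held 477, 102 and 389 normalised reads and the wild type 225, 420 and 531. The difference between the temperatures in its log2 ratio was -2.91 with a standard error of 1.06, which did not pass (limma adjusted p = 0.716). edgeR called 1 site as well, and limma called 4 without ago1d replicate 1 at 28 °C and 2 without its replicate 2 or without ago1d replicate 1 at 22 °C.

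Between 22 °C and 28 °C in the wild type, limma called 0 of the 206 shared sites, with 6 at an unadjusted p under 0.05, and edgeR called 0 with 7. At the miR160 site of LOC_Os10g33940.1 the log2 difference was 0.39 with a standard error of 0.10 (limma adjusted p = 0.541); with zeros of the kind above taken as missing at other sites, this site passed as the only call, 1 of 206.

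Sites with a lower pairing penalty had higher wild-type values over all classes together. At 28 °C the median wild-type value was 361.5 at miRNA sites and 18.3 at 21-nt phasiRNA sites. No correlation was run within a class, so pairing was not told apart from class or transcript level. Across the sites, which are not independent replicates, the pairing penalty score correlated with the wild-type value at 28 °C (Pearson's r = -0.501, Spearman's rho = -0.353) and at 22 °C (r = -0.509, rho = -0.34), each with a permutation p of 1e-05, the smallest that the permutations can give (adjusted over 4 relations, 2e-05 for r and 1.33e-05 for rho). With the log2 ratio of ago1d to wild type the correlation was weaker, at 28 °C r = -0.178 (permutation p = 0.0002, adjusted 0.000267) and rho = -0.21 (permutation p = 1e-05, adjusted 1.33e-05), and at 22 °C r = -0.094 (permutation p = 0.0523, adjusted 0.0523) and rho = -0.163 (permutation p = 0.0009, adjusted 0.0009). Read level and the choice of pairs on wild-type reads were not told apart from pairing here. Of sites with under 5 reads per library, 78.6% were lower in ago1d at 28 °C and 78.1% at 22 °C. Among sites of category 0 in a wild-type library, also chosen on the wild type, the correlations with the ratio were r = -0.1 (permutation p = 0.298) and rho = -0.191 (permutation p = 0.0432) at 28 °C. At 22 °C they were r = -0.16 (permutation p = 0.101) and rho = -0.282 (permutation p = 0.00316).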

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

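All tests of explanations in this part, the count tools and the zeros taken as missing were chosen after the results were seen. At position 581 of LOC_Os02g47280.2 the effect of ago1d differed between 22 °C and 28 °C by -11.25 on the log2 scale in the limma interaction test (adjusted p = 7.61e-09), which is what marked it. The site was listed at 0 in all 3 ago1d libraries at 22 °C. Of 100 splits of the 12 libraries, 12 gave at least 1 call in that comparison, up to 2, so a call by an arbitrary grouping of libraries is not excluded. No shared site moved one way in every sample at one temperature and the other way in every sample at the other: 0 of 206, where chance would give 1.0.

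Sites called lower in ago1d while listed at 0 there, 7 at 28 °C and 2 at 22 °C, may have zeros because the reads were listed under a near-identical sRNA whose pair is not in the table. Other transcript forms of the same genes were looked up for reads in the same libraries, though that account can hold without them. At 28 °C 8 of the 10 zeros stood beside at least 200 normalised reads at another form, and at 22 °C 4 of 4 did. Such reads show that these genes were still cut in those libraries. They do not test under which small RNA the missing reads were listed. That cleavage of these genes was lost in all ago1d libraries is argued against. Called sites included, a listed site held at least 200 in 2 or 3 ago1d libraries for 6 of 6 genes at 28 °C. At 22 °C this held for 2 of 2. For the genes at 28 °C with no other listed site, these reads were at the called site itself, in ago1d replicates 2 and 3. The remaining zeros at 28 °C are in ago1d replicate 1, at the sites of 21_PHAS_phasi22_seq29 and of a miR396 sRNA, whose genes have no other listed site, so the source of these zeros stays open.

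More sites were lower than higher in ago1d, at 28 °C and at 22 °C. Fewer reads in the ago1d libraries do not account for it, since their mean relative depth was 99.7% of the wild type at 28 °C and 99.2% at 22 °C. Selection of pairs on wild-type reads is a candidate explanation: pairs chosen by 1 wild-type library were detected in only 50.9% of the other wild-type libraries at 28 °C and 52.5% at 22 °C, close to 52.6% and 50.3% in ago1d. Zeros of pairs whose site was listed under another small RNA lower these shares as well. In the simulated selection 56.4% of listed sites were lower with no change and 90.7% with all sites lowered to 50%. The shares here were 74.6% and 70.4%. The simulated filter and read numbers differ from the real ones, so the size of the selection effect is not settled. With the selecting library among the wild-type ones, the mean log2 difference of these pairs was -0.92 at 28 °C and -1.09 at 22 °C. That library was chosen for its reads, which lowers these values whatever ago1d does. They therefore cannot test less cleavage as the whole cause. In libraries that did not select the pairs the mean log2 difference was 0.07 (95% bootstrap interval, -0.15 to 0.28) at 28 °C and -0.08 (-0.35 to 0.19) at 22 °C. Both intervals include no change. Less cleavage within these intervals stays open, and they do not cover the spread between libraries. In detection the differences were 1.7 points (-1.3 to 4.7) at 28 °C and -2.2 points (-6.1 to 1.7) at 22 °C. Wild-type reads thinned to 50% would give -5.3 and -7.3.

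At the other_22_seq216 site of LOC_Os02g18750.1 the fall in ago1d at 22 °C could reflect less transcript or less slicing. Other listed sites of the gene held 8 reads in the wild type and 0 in ago1d, but they too were kept for wild-type reads, so transcript level and slicing cannot be told apart here. Whether the fall belongs to 22 °C is also open, since the interaction gave a limma adjusted p of 0.716.

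For the site counts of ago1d against the wild type, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 8 sites at 28 °C and the highest other split 2, and at 22 °C the real split gave 11 and the highest other 1. For temperature in the wild type the real split gave 0 and the highest other 0.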

How the results depend on the processing

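The count tools, a pseudocount of 20, the treatment of zeros, the split by reads under 5 and all alternatives of the temperature comparisons were added after the data were seen. The 8 sites at 28 °C became 0 with pairs in place of sites, 0 with at least 10 reads, 0 in DESeq2 and 0 in edgeR per gene, 1 in edgeR (also 1 with TMM and 1 with DESeq2 size factors), 1 with zeros taken as missing, 2 with median scaling, 2 with quantile normalization (1 lower, 1 higher), and 3 with a pseudocount of 0.5 or 1 value per gene. The 11 sites at 22 °C became 1 with pairs, 2 in DESeq2, 2 in edgeR with TMM and 2 in edgeR per gene, 4 with median scaling (4 lower, 0 higher) or at least 10 reads, 5 without scaling, 5 with quantile normalization (4 lower, 1 higher), 5 in edgeR (3 lower, 2 higher) and 5 per gene, and 6 with zeros taken as missing. The cause was not tested. Leaving out 1 library gave 0 to 8 sites at 28 °C (0 without wild-type replicate 1, 2 or 3) and 1 to 4 at 22 °C (1 without wild-type replicate 1, 2 or 3). Without a wild-type library some sites had no read left in any library, which enters limma's estimate of spread and limits these counts. The interaction count of 1 became 0, and the wild-type temperature count of 0 became 1, with zeros taken as missing; leaving out 1 library gave 1 to 4 interaction calls, 4 without ago1d replicate 1 at 28 °C and 2 without its replicate 2 or without ago1d replicate 1 at 22 °C.

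Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated between -0.094 and 0.033. With the number as a block limma called 0 sites at 28 °C and 1 at 22 °C, and edgeR 5 and 10.

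The share of sites lower in ago1d fell to 58.6% at 28 °C (exact p = 0.12) and 47.2% at 22 °C (exact p = 0.93) with at least 10 reads, and to 55.1% at 22 °C with category 0 (exact p = 0.0598). The class difference of 21-nt phasiRNAs and miRNAs at 22 °C turned to 0.24 with at least 10 reads (permutation p = 0.207) and was -0.89 with sites under 5 reads (permutation p = 0.0763); without 1 library it ranged from -1.62 to -0.80 at 28 °C and from -1.38 to -0.55 at 22 °C. The shared share of sites rose from 48.4% to 60.5% with scores up to 4 and 62.8% with category 0. The fall at LOC_Os10g33940.1 at 28 °C turned to 0.01 in edgeR with DESeq2 size factors, which moved all sites by a median of 0.22. The cause was not tested. Pearson's r of score and ratio became -0.1 at 28 °C with category 0 (permutation p = 0.298) and -0.098 at 22 °C with a pseudocount of 0.5 (permutation p = 0.0436). Of 199 alternatives of the main results 145 kept direction and threshold or stayed within 1.5-fold, among them all of the gene lists, categories and rank correlations with the score. Some of these could hardly differ. The gene lists gave 0 calls throughout on 4 to 6 sites, and pairs in place of sites only add rows without reads to the categories. The number 145 is therefore no measure of robustness. A 21-nt phasiRNA site had a median of 1.0 read per wild-type library, which limits most per-site results of that class.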

Other observations

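The tests of this part were chosen after the data were seen. Small RNAs outside the miRNA class included 10 that share a stretch of 17 nt with a listed miRNA, among them relatives of miR160, miR166, miR171, miR820, miR1425 and miR2118. They made 20 of the 109 pairs of other small RNAs at 28 °C and 17 of 94 at 22 °C, and carried 57.7% and 64.2% of that class's wild-type value. The largest of these sites, under other_21_seq552, held 4577 ± 699 normalised reads in the wild type and 3554 ± 647 in ago1d at 28 °C (SD, n = 3). Among the listed 21-nt phasiRNAs, 0 shared such a stretch with a listed miRNA.

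miR408 had 6 sites at 28 °C and 4 at 22 °C. At 28 °C 2 were lower and 4 higher in ago1d, with 812 ± 95 normalised reads in the wild type and 797 ± 223 in ago1d over all of them, and at 22 °C 4 were lower and 0 higher, with 650 ± 71 and 497 ± 270 (SD, n = 3, not tested). miR528 sites summed to 1951 ± 501 in the wild type and 2927 ± 226 in ago1d at 28 °C, and to 1525 ± 506 and 1380 ± 66 at 22 °C (not tested).

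A hypothesis was that 21-nt phasiRNA pairs with a low ratio of ago1d to wild type may have lost copies of the small RNA, as the tables list a direction for each small RNA at S7-8 and S9, against a reference the headers do not state. At 28 °C 72 of the 246 pairs had a small RNA listed as down at S7-8 and 69 at S9, and at 22 °C 64 and 47 of 266. Targets of small RNAs listed as down differed from those listed as non in their median log2 ratio by 0.18 (S7-8) and -0.11 (S9) at 28 °C and by 0.02 and 0.01 at 22 °C. All 4 had an adjusted permutation p of 0.795, so the test did not separate them.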
